A study of Rattus norvegicus with 11 samples.

How the data were processed

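RNA was measured by sequencing in 11 libraries labelled as cerebellar cortex of 10-week-old Sprague-Dawley rats. The labels give 6 libraries of rats homozygous for the R571X mutation of CSB (the protein encoded by Ercc6), 2 of heterozygous rats and 3 of wild-type rats. The titles call the 2 libraries heterozygous, while their genotype label writes the second allele only as a minus sign. They are called heterozygous here. Nothing in the labels says that each library came from a separate animal, so p-values measure the spread between these samples, which could in part be technical. Per the labels' protocols, tissue was frozen, RNA was extracted with Trizol, and libraries made with a TruSeq RNA kit were sequenced in paired-end mode.

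Each deposited file holds 1 library. Per the submitters' processing notes, FastQC, HISAT2 2.0.4 and the rat build rn6 were used. The read counter, the annotation version and the strand setting are not given in the sources used here. The deposited values are a normalized read signal per gene, in which the authors divided the reads of each gene by 1 size factor per library. At a tolerance of 0.001, 100% of the deposited signal values in each library were whole multiples of the value of 1 read, so the reads were recovered. The factors ranged from 0.807 to 1.39. The reads assigned to features were 8723823, 6028086, 7458681, 5450053, 5766512 and 7813701 in homozygous replicates 1 to 6, 5406669 and 5999484 in the heterozygous replicates, and 5771660, 6785567 and 7705525 in the wild-type replicates.

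The size factors showed that the libraries had been normalized in 2 separate sets. Median-of-ratios factors computed from the recovered reads equalled the deposited ones to within 3.6e-15 when homozygous replicates 1 to 3 were taken with the heterozygous libraries (set 1), and homozygous replicates 4 to 6 with the wild-type libraries (set 2). The sets list 24436 and 24792 features and share 23093. Of the shared features, 11925 have Ensembl identifiers and 11168 are assembled features with no gene name. Features listed in only 1 set (1343 and 1699) had at most 186 and 464 reads in total and entered no test. Scaling all 11 libraries together moved them by -0.74% to 1.54% against their own set.

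Groups were compared with limma 3.58.1 (R 4.3.3, empirical Bayes with a mean-variance trend) on log2(value + 1), over the 20956 shared features with a mean of at least 1. One fit of the 11 libraries held the group and the set. Homozygous was thereby compared with wild type inside set 2 (3 against 3 libraries) and with heterozygous inside set 1 (3 against 2). Heterozygous and wild-type libraries share no set, so their difference is the first contrast minus the second and carries the error of both. The set term is a departure from the design fixed before the data were examined, which had 3 groups and no covariate. It was added because values of separately normalized tables are tested only within a table. The fit without it is given as an alternative. Fold changes are on the log2(value + 1) scale, which understates the change of features with few reads. The threshold was a Benjamini-Hochberg adjusted p under 0.05.

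The gene lists were fixed at the same stage as the design. Of 37 lists, 33 had at least 5 tested members and were tested as sets with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation. Members were also counted after adjustment over the list alone. Mean log2 CPM per list and library (TMM scaling of all 11 libraries in edgeR 4.0.16, prior count 2) was compared between the 6 homozygous and 3 wild-type libraries with a two-sided exact permutation test over 84 arrangements. The smallest p it can give is 0.0119. For 3 libraries against 3 the smallest two-sided p is 0.1.

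Genes are named by a rule fixed beforehand. Ercc6 is always named. In each comparison, up to 12 genes per direction with the largest fold change are named among those past the threshold with a mean of at least 1 and no overlap between the groups, leaving out names that start with LOC, RGD, AABR or AC0 and features with no gene name. Where no gene passed, the 4 genes per direction with the smallest p are named as having missed the threshold. Up to 4 members with the smallest p are named for each list described.

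The same models were tested on simulated data before use. Reads were drawn from the real means, library sizes and spread, with 100 features changed 2-fold and 100 changed 4-fold. The changed features were taken only from those with means well above the minimum for testing. Recovery among features with few reads was therefore not measured. For homozygous against wild type the limma fit recovered 4% of the 2-fold and 70% of the 4-fold changes, with 9 false calls among 20836 features. For homozygous against heterozygous it recovered 4% and 59%, with 5 false calls. For heterozygous against wild type it recovered 0% and 10%, with 0 false calls. Most changes of about 2-fold are therefore below what these libraries can detect one gene at a time. As a share of all calls, the false calls exceeded 0.05 in both comparisons of homozygous libraries. In these simulated data the limma fit was therefore less strict there than its threshold states.

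Alternatives were edgeR on the recovered reads (with 3 scalings and a robust fit), limma-voom, DESeq2 1.42.0, other filters and pseudocounts, other sets of libraries in the fit, the replicate number as a block, presence of reads of a Y-linked gene as a covariate, and the removal of each library in turn. Of these, edgeR with TMM scaling and the set term, the fits without the set term, the Y-linked covariate and the exact test over list means were chosen after seeing the data. Reads were recovered and tables and figures made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Where a named gene lies under another feature on the same strand, its reads may have been split between them. The major histocompatibility genes (RT1), the ribosomal protein genes and the mitochondrial genes also share reads with near-identical copies or overlapping features, so their values are uncertain. No coordinates were taken from the reference table given with the data, because it is of another build.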

Results

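The study compared brain tissue of rats that carry a truncating mutation of CSB, the DNA repair protein mutated in Cockayne syndrome, with that of carriers and of wild-type rats, to see how loss of CSB affects gene expression. There were 6 homozygous, 2 heterozygous and 3 wild-type libraries. Each held between 5406669 and 8723823 reads assigned to features, of which 25.1% to 31.5% fell on assembled features with no gene name. Libraries of 1 group differed by far more than sampling noise, with a chi-square per degree of freedom of at least 13.3 between any pair, so none was the same library sequenced again. Separate preparations from 1 animal are not ruled out by this.

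Ercc6, the gene that encodes CSB (chromosome 16, 8734035 to 8804610, rn6, plus strand), was read in every library and was lowest in the homozygous ones. The homozygous libraries held 132 ± 28.6 normalized reads (SD, n = 6), the heterozygous 203 ± 35.2 (n = 2) and the wild-type 353 ± 56.0 (n = 3). Each of the 6 homozygous libraries (85.8 to 158) lay below both heterozygous libraries (178 and 228), and these lay below all 3 wild-type libraries (295 to 407). With all libraries scaled together, the 6 homozygous libraries had 37.2% of the wild-type level (two-sided exact permutation p = 0.0119, the smallest that 84 arrangements allow). These levels are set across the 2 separately normalized sets, and within the homozygous genotype set 2 had 70.5% of the level of set 1 (109 against 156, exact p = 0.1, the smallest possible). Within set 2, Ercc6 fell by 1.69 on the log2 scale (SE 0.22, adjusted p = 0.0171 in limma, 3 against 3 libraries). Within set 1, the homozygous libraries held 156 ± 2.61 normalized reads (n = 3) and the heterozygous 203 ± 35.2 (n = 2), a log2 difference of -0.37 (SE 0.25, adjusted p = 0.576).

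**Figure D1:**
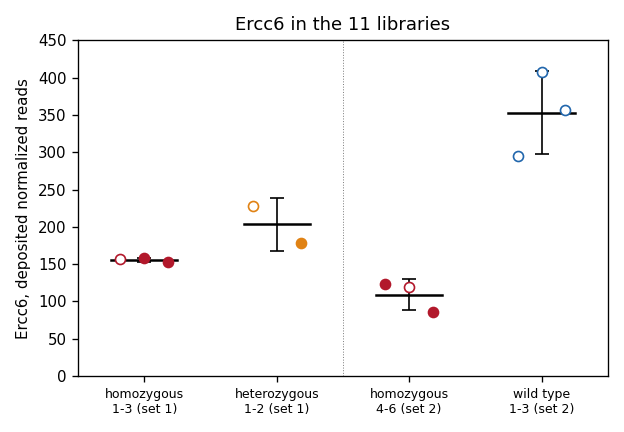
Normalized reads of Ercc6 in each library (vertical axis, deposited unit), with libraries grouped by genotype and by the set in which they were normalized. Points are libraries, filled where reads of the Y-linked gene Eif2s3y were present, and lines and bars are means and SDs. Homozygous libraries sit between 85.8 and 158, heterozygous ones at 178 and 228, and wild-type ones between 295 and 407.

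The libraries differed in sex-linked and regional transcripts in ways the labels do not describe. The Y-linked gene Eif2s3y had between 669 and 1875 reads in homozygous replicates 2, 3, 4 and 6 and in heterozygous replicate 2, and at most 1 read in the other 6 libraries, among them all 3 wild-type libraries. Ddx3y, also Y-linked, had 1 to 13 reads in each library, with 2, 9 and 8 in the wild type, and did not follow Eif2s3y. Presence of Y-linked reads below refers to Eif2s3y alone. Forebrain markers were present in all 11 libraries. Neurod6, a transcription factor of cortical and hippocampal neurons, ranged from 45.2 to 310 CPM, Emx1, a transcription factor of the developing cerebral cortex, from 31.9 to 87.6 CPM, and the assembled feature over Tbr1, which marks deep cortical neurons, from 77.8 to 281 CPM. Pcp2, a marker of cerebellar Purkinje cells, was listed in set 2 alone, with 2 reads in wild-type replicate 1 and 0 in the other 5 libraries. Only 3 of 15 genes on the Purkinje list and 1 of 14 on the brainstem list were tested, too few for a test of either list. Hoxb3, a hindbrain gene, had 63 reads in homozygous replicate 6 and at most 6 in any other library.

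**Figure D2:**
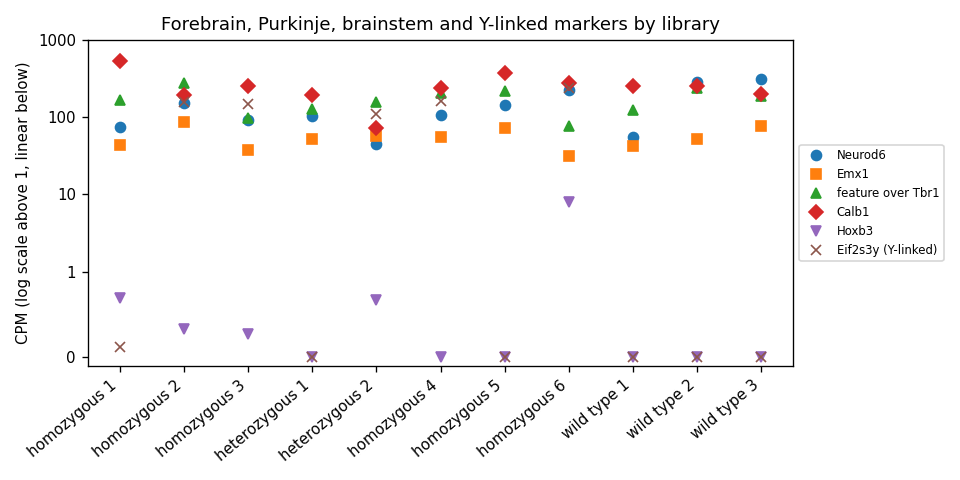
Abundance in CPM of forebrain markers (Neurod6, Emx1 and the assembled feature over Tbr1), the Purkinje list gene Calb1, the brainstem list gene Hoxb3 and the Y-linked gene Eif2s3y in each library. The vertical axis is logarithmic above 1 and linear below. The 3 forebrain features were at 31.9 CPM or more in every library, while Eif2s3y was near 0 in 6 of the 11.

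The first comparison asked what changed in homozygous relative to wild-type tissue. Genes of the interferon response and of antigen presentation were higher in the homozygous libraries as groups with a preset correlation, but not with an estimated one (adjusted p = 0.319 with an estimated correlation for both lists). Ercc6 was the only named gene past the threshold in limma. Cxcl10, a chemokine induced by interferon (chromosome 14, 17210733 to 17212930), held 69.9 ± 8.79 normalized reads in homozygous replicates 4 to 6 and 10.4 ± 5.87 in the wild type (SD, n = 3 each), a log2 difference of 2.78 (SE 0.57). Cd74, the invariant chain of major histocompatibility class II (chromosome 18, 56071478 to 56080849), held 2273 ± 340 against 569 ± 581 (log2 difference 2.46, SE 0.49). Neither passed over all genes (adjusted p = 0.257 and 0.227 in limma).

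Of 16 interferon response genes tested, 14 had a positive log2 difference with a mean of 1.20. None passed over all features and 10 passed when adjusted over the list alone. Camera with the preset correlation placed the list above other genes (adjusted p = 7.04e-14), but not with an estimated correlation (adjusted p = 0.319 with an estimated correlation). Ifit3, a protein induced by interferon, held 143 ± 33.7 normalized reads against 29.2 ± 12.8 (log2 difference 2.31, SE 0.50), Ifi27 held 4771 ± 727 against 2039 ± 389 (1.23, SE 0.24), and Ifit2 held 234 ± 10.6 against 106 ± 15.6 (1.15, SE 0.27). Their adjusted p over all features was 0.305, 0.227 and 0.436 in limma. Under the other settings (see the section on processing) the log2 difference ran from 0.347 to 1.245 for Ifi27, 0.504 to 1.165 for Ifit2 and 1.555 to 2.317 for Ifit3. The list mean ran from 0.798 to 1.197.

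Of 15 antigen presentation genes tested, 13 had a positive difference with a mean of 1.19. None passed over all features and 10 passed when adjusted over the list alone (camera adjusted p = 1.79e-11 with the preset correlation, adjusted p = 0.319 with an estimated correlation). RT1-Db1, a class II chain, held 318 ± 114 normalized reads against 75.1 ± 67.7 (log2 difference 2.36, SE 0.50). RT1-CE5, of class I, held 30.5 against 7.07 (2.21, SE 0.59), and Psmb8, a subunit of the immunoproteasome, 206 ± 26.3 against 98.0 ± 41.2 (1.15, SE 0.32). Their adjusted p over all features was 0.277, 0.509 and 0.529 in limma. Under the other settings the log2 difference ran from 1.566 to 2.867 for RT1-Db1, 0.135 to 2.391 for RT1-CE5 and 0.815 to 1.092 for Psmb8. The list mean ran from 0.684 to 1.245. RT1 genes share reads with near-identical copies and are uncertain. Tap2 (-0.96, SE 0.59) and RT1-DMa (-0.04, SE 0.37) had negative differences.

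**Figure D3:**
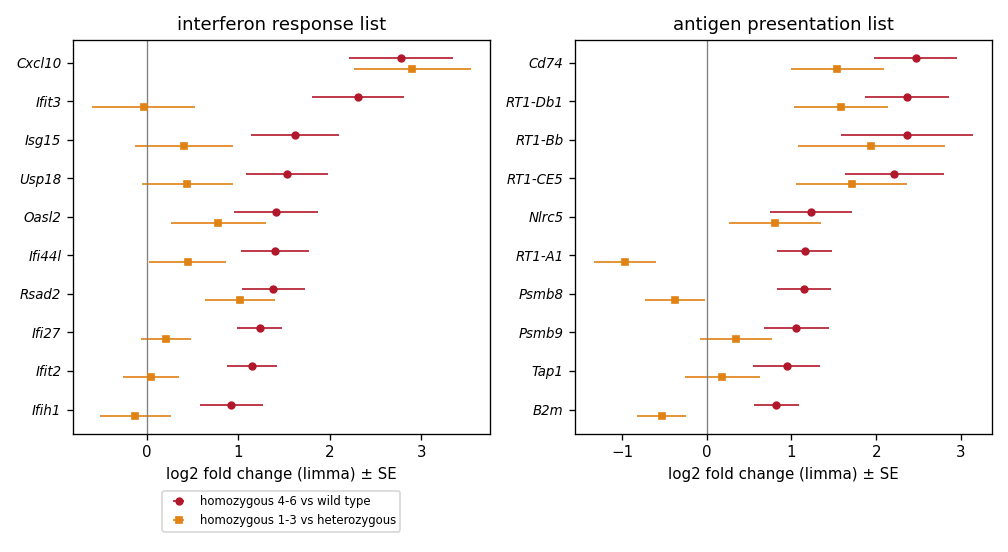
Log2 fold changes (horizontal axis, limma, bars are standard errors) of the 10 members of the interferon response list (left) and the 10 of the antigen presentation list (right) that passed in homozygous against wild type when adjusted over the list alone, for homozygous replicates 4 to 6 against wild type and for homozygous replicates 1 to 3 against heterozygous libraries. Members that did not pass are not shown, so the first comparison lies above 0 by selection, while the second comes from other libraries.

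The homozygous libraries of set 1 took no part in that contrast. Their interferon response list means (homozygous replicates 1 to 3) were 3.13, 3.20 and 4.03 log2 CPM, against 3.25, 2.34 and 2.58 in the wild type, and those of antigen presentation 3.43, 3.24 and 3.49, all below the highest wild-type library (3.57). Over all 6 homozygous and 3 wild-type libraries, scaled together, the mean of the interferon response list was 3.67 ± 0.43 log2 CPM (SD, n = 6) against 2.72 ± 0.48 (n = 3), and 4 of the 6 homozygous libraries lay above all wild-type libraries (two-sided exact permutation p = 0.0476, 0.524 after adjustment over 33 lists). For antigen presentation the means were 3.64 ± 0.31 and 2.76 ± 0.73, with 3 of 6 libraries, those of set 2, above all wild-type ones (exact p = 0.0476, adjusted 0.524). The mean of the p53 target list, genes induced by DNA damage, was 4.03 ± 0.10 against 3.73 ± 0.16, and all 6 homozygous libraries lay above all 3 wild-type libraries (exact p = 0.0119, the smallest possible, adjusted 0.393). Both heterozygous libraries (3.93 each) also lay above all wild-type libraries (at most 3.86) and within the homozygous range. Within set 2, 9 of 14 p53 targets had a positive difference, none passed over all features or when adjusted over the list alone, and camera did not call the list (adjusted p = 0.141).

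**Figure D4:**
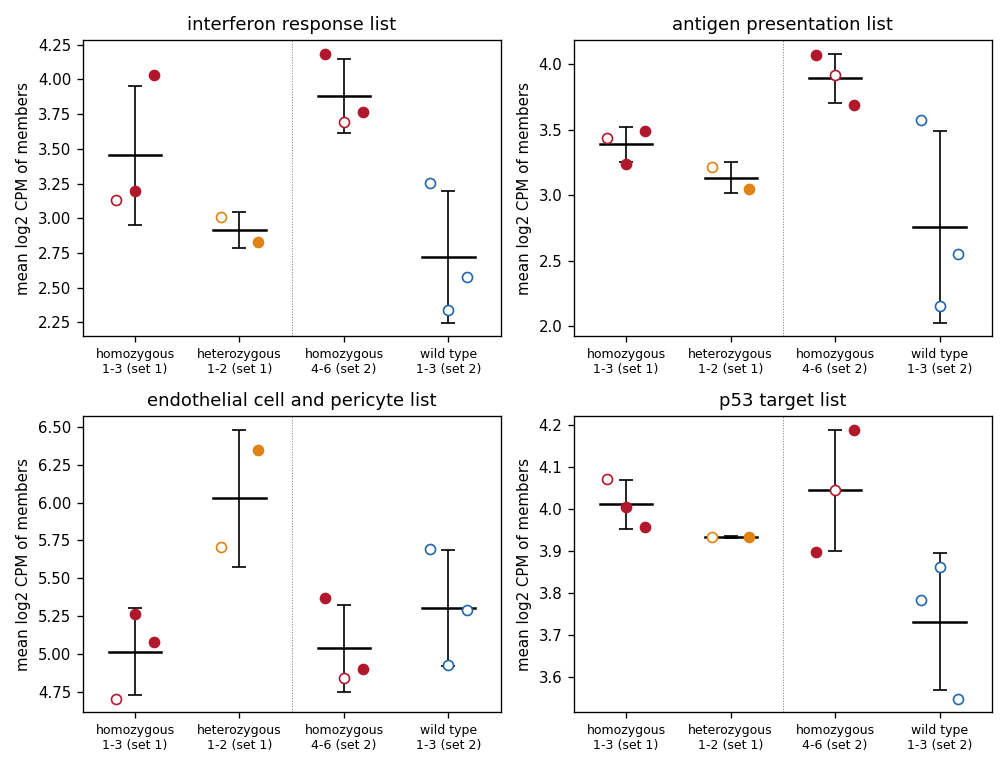
Mean log2 CPM (vertical axis) over the tested members of 4 gene lists in each library, by genotype and set. Points are libraries, filled where Eif2s3y reads were present, and lines and bars are means and SDs. All 6 homozygous libraries lie above the wild-type libraries for p53 targets, 4 of 6 do so for the interferon response list, and both heterozygous libraries lie above every other library for the endothelial cell and pericyte list.

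Another 5 lists were called in this comparison with the preset correlation, and none of them with an estimated one. Inhibitory interneuron genes had a mean log2 difference of 0.58 over 8 members (adjusted p = 0.0183, 0.665 with an estimated correlation). Slc32a1, the vesicular transporter of GABA and glycine, held 1338 ± 540 against 653 ± 20.1 normalized reads. It lies under another feature on the same strand. Nuclear genes of the respiratory chain had a mean of 0.27 over 17 members (adjusted p = 1.81e-05, 0.665 with an estimated correlation), with Atp5o at 0.56 (SE 0.17) and Cox7a2 at 0.53 (SE 0.19). Ribosomal protein genes had a mean of 0.37 over 24 members (adjusted p = 5.09e-06, 0.665 with an estimated correlation), with Rpl38 at 1.24 (SE 0.43) and Rps3 at 0.57 (SE 0.23). Antioxidant genes had a mean of 0.27 over 12 members (adjusted p = 0.0483, 0.684 with an estimated correlation), with Sod1 at 0.41 (SE 0.16) and Gpx3 at 0.86 (SE 0.36). Rpl38 held 91.9 ± 70.0 normalized reads against 32.3 ± 6.88, and Gpx3 548 ± 347 against 269 ± 28.3. With 1 library left out, their differences fell to as little as 0.663 and 0.374. Respiratory chain genes of the mitochondrial genome had a mean of -0.85 over 6 members (adjusted p = 0.00646, 0.665 with an estimated correlation), with Mt-nd4 at -0.95 (SE 0.50) and Mt-nd5 at -0.81 (SE 0.48). The last 2 lie under another feature on the same strand, and ribosomal protein genes share reads with their pseudogenes, so both lists are uncertain. No member of these 5 lists passed over all features, and 1, of the interneuron list, passed when adjusted over the list alone. Over all 6 homozygous and 3 wild-type libraries, scaled together, the differences were 0.42, 0.03, 0.17, 0.23 and -0.65 log2 CPM in the order above (two-sided exact permutation p = 0.298, 0.929, 0.5, 0.119 and 0.131). Without homozygous replicate 6 the interneuron mean was 0.20, the nuclear respiratory chain mean 0.10, the antioxidant mean 0.16 and the mitochondrial mean -0.40 (Mt-nd4 -0.31, Mt-nd5 -0.16), and without wild-type replicate 2 the ribosomal mean was 0.22. Without homozygous replicate 6 the interneuron, mitochondrial and antioxidant lists were not called, the first 2 of these also not without wild-type replicate 1, and the antioxidant list not without homozygous replicate 2 or wild-type replicate 2 or 3.

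In all, 8 of 20956 features passed in limma, 3 higher and 5 lower in the homozygous libraries, and 7 of them have no gene name. One on chromosome 5 (150490328 to 150491659) held 1.7 to 5.8 normalized reads in homozygous replicates 4 to 6 and 167 to 348 in the wild type (log2 difference -5.83, SE 0.48, adjusted p = 0.000201). One on chromosome 6 (147447271 to 147447613) held at most 0.8 reads against 51.6 to 122 (adjusted p = 0.000115), but 51.2 to 126 in homozygous replicates 1 to 3. One on chromosome 19 (28039685 to 28044531) held 0 against 6.6 to 18.3 (adjusted p = 0.0163), but 35.7 to 49.8 in homozygous replicates 1 to 3. The other unnamed features also set the heterozygous libraries apart from the wild type, with 6.2 and 6.1 for the one on chromosome 5, so they were not particular to homozygous tissue. These features were chosen for the text after their values were seen. DESeq2 called 39 features, 26 higher and 13 lower, while edgeR called 5 and limma-voom 2. The DESeq2 calls held Cxcl10, Cd74, Ifi27, Ifit2, Ifit3 and RT1-Db1, and also the Y-linked Eif2s3y and other genes. For Ercc6, homozygous vs wild type, the call was lost without homozygous replicate 4 (adjusted p = 0.0685), without homozygous replicate 6 (0.0644), without wildtype replicate 2 (0.0766), without wildtype replicate 3 (0.148) and with Y-linked reads as a covariate (0.187, log2 difference -1.57). It was also lost with only the libraries of these 2 groups in the fit and against the mean of the wild-type and heterozygous groups. With the replicate number as a block, which set homozygous replicates 1 to 3 against wild type, it was lost too (-1.16, adjusted p = 0.673). Its log2 difference stayed between -1.81 and -1.53 with each library left out. Cd74 and RT1-Db1 passed the threshold without wildtype replicate 1 (adjusted p = 0.000125 and 0.0076).

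The second comparison set homozygous against heterozygous tissue. Genes of endothelial cells, which line blood vessels, were lower in homozygous replicates 1 to 3 as a group with a preset correlation, but not with an estimated one (adjusted p = 0.528 with an estimated correlation). Thsd1 and Fgd5, known from endothelium, were among the 4 genes with the smallest p in that direction, and each missed the threshold. No feature passed in limma (0 of 20956, with 2539 at an unadjusted p under 0.05). edgeR also called 0 and DESeq2 called 207, of which 144 were lower in the homozygous libraries, among them Vwa1, Thsd1, Slc9a3r2, Fgd5, Slc2a1, Tek and Rgs5.

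Of 8 endothelial cell and pericyte genes tested, all 8 had a negative log2 difference with a mean of -1.09. None passed over all features and 5 passed when adjusted over the list alone (camera adjusted p = 6.97e-06, adjusted p = 0.528 with an estimated correlation). Slc2a1, the glucose transporter of the blood-brain barrier, held 4961 ± 1389 normalized reads (SD, n = 3) against 14578 ± 7009 (n = 2), a log2 difference of -1.51 (SE 0.34). Tek, the angiopoietin receptor, held 325 ± 12.9 against 903 ± 178 (-1.46, SE 0.34). Rgs5, of pericytes, had a difference of -1.09 (SE 0.31) and Emcn, of endothelium, -1.05 (SE 0.33). Adjusted p over all features was 0.203, 0.215, 0.263 and 0.293 in limma for these 4 genes. Lists of other non-neuronal cells went both ways, and none was called. Means were negative for blood (-0.62, 8 of 10 features negative, camera adjusted p = 0.202) and microglia (-0.35, 6 of 8 negative, adjusted p = 0.164). They were positive for meningeal fibroblasts (0.95, 7 of 8 positive, adjusted p = 0.267) and choroid plexus (0.64, 8 of 11 positive, adjusted p = 0.608). Astrocyte, oligodendrocyte and oligodendrocyte precursor genes had means of -0.059, 0.033 and -0.236.

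The genes with the smallest p missed the threshold. Vwa1 (chromosome 5, 173216741 to 173222440) held 870 ± 127 against 3195 ± 595 normalized reads, Thsd1 (chromosome 16, 74680621 to 74710704) 307 ± 42.1 against 1110 ± 131, Slc9a3r2 337 ± 55.2 against 1005 ± 136, and Fgd5 179 ± 9.51 against 624 ± 188, with adjusted p = 0.16 for the first 2 and 0.164 for the others. Among genes higher in the homozygous libraries, Klf5, a zinc finger transcription factor, held 313 ± 84.7 against 74.6 ± 33.0 (adjusted p = 0.164). Pnma1 held 104 ± 38.9 against 27.1 ± 5.51 (adjusted p = 0.164) and Abca8 134 ± 52.8 against 38.8 ± 15.2 (adjusted p = 0.2). Vwa5b1 held 23.6 ± 15.0 and no read in either heterozygous library, which makes it at least 12.8-fold higher against a floor of 3 reads over the group (adjusted p = 0.165). Vwa5b1 and Slc9a3r2 lie under another feature on the same strand.

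Another 4 lists were called with the preset correlation and none with an estimated one. Circadian clock genes had a negative log2 difference in each of 8 members, none of which passed alone (mean -0.76, camera adjusted p = 0.0035, 0.245 with an estimated correlation), with Dbp, an output gene of the clock, at -0.76 (SE 0.28) and Cry1, a repressor within it, at -0.56 (SE 0.21). This list was fixed beforehand as a check of handling and time of day, which were not tested here. For homozygous against wild type its mean was -0.03. The heterozygous libraries had the highest list means (4.96 and 5.33 log2 CPM, the next 4.90 in wild-type replicate 1). Ribosomal protein genes had a mean of -0.42 over 24 members (adjusted p = 6.97e-06, 0.851 with an estimated correlation), with Rpl35 at -0.95 (SE 0.25). Mitochondrial genome genes had a mean of -1.07 over 6 members (adjusted p = 0.00422, 0.699 with an estimated correlation), and the libraries' share of reads on the mitochondrial genome was 0.433% to 0.788% in homozygous replicates 1 to 3 and 1.44% and 1.46% in the heterozygous ones. Only 1 of the 6 members lies under no other feature on the same strand. Mt-nd1, with the smallest p, had few reads (0.24 normalized reads against 3.69, log2 difference -1.97). Granule neuron genes had a positive log2 difference in each of 5 members (mean 1.16, adjusted p = 0.0476, 0.495 with an estimated correlation), with Neurod1, a neuronal transcription factor, at 2.10 (SE 0.52), under another feature on the same strand. Slc17a7, the vesicular glutamate transporter, is on that list and is also abundant in forebrain neurons (log2 difference 0.40, SE 0.26). No member of these 4 lists passed over all features, and 1, of the granule list, passed when adjusted over the list alone. The circadian list was not called without heterozygous replicate 2, the mitochondrial list not without heterozygous replicate 1, and the granule list not without either of these or without homozygous replicate 1 or 3.

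The 2 comparisons share no library in their contrasts. Across genes, which are not independent replicates, their log2 differences had a Pearson correlation of 0.08 over 20956 features, 0.30 over the 16 interferon response genes and 0.79 over the 15 antigen presentation genes. Of genes named above for the first comparison, Cxcl10 had a log2 difference of 2.90 against the heterozygous libraries (SE 0.64, adjusted p = 0.2, or 0.00911 over its list alone). Cd74 (1.54, SE 0.55) and RT1-Db1 (1.59, SE 0.55) did not pass (adjusted p = 0.331 and 0.324, or 0.0805 for each over the list alone), and Ifit3 had a difference of -0.03. The interferon response list itself was not called against the heterozygous libraries (12 of 16 members positive, mean 0.61, camera adjusted p = 0.102), nor was antigen presentation (8 of 15 positive, mean 0.28, adjusted p = 0.748).

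The third comparison, of heterozygous with wild-type tissue, asked what 1 mutant copy changes. It joins the 2 sets through the homozygous libraries and had the least power. Ercc6 had a log2 difference of -1.32 (SE 0.33, adjusted p = 0.585), and no feature passed in limma (0 of 20956, with 1669 at an unadjusted p under 0.05). edgeR called 0 and DESeq2 called 27, among them Fcrl2, RT1-A1, Vwa5b1 and the Y-linked Eif2s3y. Values below are normalized reads of the heterozygous (n = 2) and wild-type (n = 3) libraries, which come from different sets, so they need not equal the fitted differences.

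The genes with the smallest p missed the threshold. Fcrl2, an Fc receptor-like gene, had 14.1 ± 2.46 against 112 ± 48.5 normalized reads (log2 difference -3.61, SE 0.59, adjusted p = 0.158). Lxn had 741 ± 13.1 against 414 ± 72.2 (1.25, SE 0.29) and RT1-A1, of class I, 62.1 ± 10.6 against 38.0 ± 7.08 (2.12, SE 0.49), with adjusted p = 0.585 and 0.564. Vwa5b1 had no read in either heterozygous library and 17.5 ± 9.99 normalized reads in the wild type. Col6a5 and Clnk also had none, and the wild type few. Oas1e (4.31 ± 0.92) and Mrap (3.07 ± 0.84) had reads in the heterozygous and none in the wild-type libraries. Against a floor of 3 reads over the group at 0, the difference was at least 9.51-fold for Vwa5b1, 2.47-fold for Col6a5, 1.90-fold for Clnk, 4.57-fold for Oas1e and 3.26-fold for Mrap. Adjusted p for these 5 genes lay between 0.378 and 0.585.

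Camera with the preset correlation called 9 of 33 lists in this comparison and 0 with an estimated correlation, where the lowest adjusted p was 0.501. Higher were ribosomal protein genes (mean log2 difference 0.79, 14 of 24 members past the threshold adjusted over the list alone, with Rpl35 at 1.28, SE 0.34), nuclear respiratory chain genes (0.62 over 17 members, with Cox7a2 at 0.97), antigen presentation (0.91 over 15, with B2m at 1.35), interferon response (0.59 over 16, with Ifit3 at 2.34), endothelial cell and pericyte (0.82 over 8, with Slc2a1 at 1.21), circadian clock (0.73 over 8, with Dbp at 1.04), antioxidant (0.45 over 12, with Gpx1 at 0.98) and microglia (0.71 over 8, with C1qb at 1.23). Lower were granule neuron genes (-1.11 over 5, with Neurod1 at -2.41). Their camera adjusted p with the preset correlation lay between 8.48e-11 and 0.0393, and each was 0.501 or more with an estimated correlation. No member passed over all features. The fitted differences of single members can lie well away from the direct values. Cox7a2 held 3960 ± 87.2 normalized reads in the heterozygous libraries against 3512 ± 561 in the wild type, with overlap between the groups. B2m held 16376 ± 1037 against 9760 ± 3800, and Slc2a1 14578 ± 7009 against 5238 ± 1097. Adjusted over the list alone, 3 antigen presentation genes, 1 granule gene and no member of the other 6 lists passed. On 3 groups without the set term, the means were smaller for ribosomal protein genes (0.42), nuclear respiratory chain (0.13), antigen presentation (0.405), interferon response (0.19), circadian clock (0.46) and granule neuron genes (-0.73), and the nuclear respiratory chain, interferon response and granule lists were not called. Without heterozygous replicate 2 the granule, microglia, endothelial, antioxidant and circadian lists were not called.

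None of the following cell type and tissue lists was called between homozygous and wild-type libraries. The mean log2 difference was 0.05 over 12 astrocyte and Bergmann glia genes, 0.25 over 12 oligodendrocyte genes, 0.37 over 8 microglia genes, -0.27 over 8 endothelial cell and pericyte genes, -0.07 over 10 features of the blood list and -0.09 over 7 forebrain genes, with camera adjusted p of 0.145 or more. Of the astrocyte genes, 1 passed when adjusted over the list alone, Gfap, an intermediate filament of astrocytes (log2 difference 1.235, SE 0.315, adjusted p = 0.0219 over the list and 0.484 over all features). It was named after its value was seen. The nucleotide excision repair list, which holds Ercc6, was not called (mean -0.15 over 12 genes, adjusted p = 0.86), and Ercc6 was its only member past the threshold.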

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

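Tests on microglia and blood cells and on forebrain tissue were chosen only after the results they bear on had been seen. Each of 115 readings (list means, named genes and library measures) was examined for 1 homozygous library standing far from the other 5, and 4 stood out, where chance flags about 1 in 20 groups. Homozygous replicate 6 was the highest for Gpx3 (7.22 log2 CPM against 5.47 to 6.06, a gap of 0.658 of the range) and for Prdx1 (8.85 against 7.67 to 8.09, a gap of 0.648). Homozygous replicate 4 was the highest for Rpl38 (4.74 against 2.77 to 3.33, a gap of 0.72) and for Tek (6.30 against 5.43 to 5.72, a gap of 0.667). Among the 1699 features listed in set 2 alone, which entered no comparison, 1 assembled feature with no gene name had 60 reads in homozygous replicates 4 to 6 (at least 13 in each) and 0 in the wild-type libraries.

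Interferon and antigen presentation genes were higher in homozygous than in wild-type libraries, by 1.15 log2 CPM in set 2 and by 0.914 over all 6 homozygous libraries, but the list calls were lost with an estimated correlation (adjusted p = 0.319 with an estimated correlation for both), and homozygous replicates 1 and 2 (3.28 and 3.22) lay below the highest wild-type library (3.41). Of the 84 arrangements of 6 and 3 libraries, 3 gave as large a difference (the highest of the others 1.01), so few chance arrangements reached it, although neither list passed after adjustment over all lists (exact p = 0.524 adjusted). These arrangements mix the 2 sets. Of the 10 splits within set 2, the real one gave the largest mean log2 difference over these genes (1.195, the next 0.982). That is too few splits for a share under 0.05. More microglia or blood cells would raise their markers as much. These markers together had a mean log2 difference of 0.124 (SE 0.173, 18 features) against 1.20 (SE 0.147, 31 genes). The blood list holds red-cell genes and had a mean of -0.07, while microglia genes had 0.365 with 6 of 8 positive. The standard errors treat genes that vary together as independent (estimated correlation 0.375 for microglia and 0.358 for blood). More microglia or white blood cells therefore stay open, although the microglia mean was the smaller. Other tissue in homozygous replicate 6 is argued against by a difference of 1.22 without that library. Sex stays open, since all wild-type libraries lacked Eif2s3y reads. The lowest homozygous library without them lay within the wild-type range, by -0.13 (homozygous replicate 1, at 3.28). However, homozygous replicate 5, of set 2 and also without them, lay at 3.80 against at most 3.41 in the wild type. With Eif2s3y reads as a covariate the interferon list kept a mean of 1.03. Wild-type replicate 1 lay highest among the wild type (3.41 against 2.25 and 2.56). Another stock or litter of the wild-type animals, raised below for other features, also stays open here. With the preset correlation, both lists were called higher in heterozygous than in wild-type libraries (means 0.587 for interferon response and 0.914 for antigen presentation). Scaled together, the heterozygous libraries lay at 3.11 and 2.93, within the wild-type range. An effect of the mutation stays open as a hypothesis.

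As a list, endothelial genes were lower in homozygous than in heterozygous libraries with the preset correlation only (adjusted p = 0.528 with an estimated correlation), and none passed over all features. A single outlying heterozygous library is argued against, since the lower of the 2 lay 0.448 above the highest homozygous library of its set (SD 0.285 of the 3 homozygous). Fewer vessels in the homozygous samples would lower pericyte and mural genes too, and these had a mean of -0.557 (SE 0.293, 3 genes) against -1.40 (SE 0.308) for the 5 endothelial genes, which leaves this open with so few genes. More vessel RNA in the heterozygous samples also stays open, because the lower heterozygous library exceeded the highest wild-type library by only 0.018, less than the wild-type SD of 0.383. With 2 heterozygous libraries, dissection and genotype cannot be told apart here.

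All 11 libraries carried forebrain transcripts although their labels say cerebellar cortex. Neurod6, Emx1 and the feature over Tbr1 were at 31.9 CPM or more in each library, consistent with forebrain tissue in the samples as a hypothesis. Whether cerebellar transcripts are also there stays open, since only 23.3% of the 30 Purkinje and granule genes can be read under their own name, and those include genes that forebrain neurons use too, such as Slc17a7 and Calb1, while Pcp2, which marks Purkinje cells and lies under no other feature, had 2 reads in the 6 libraries that list it. No biological explanation was tested for this pattern, because the libraries of all 3 genotypes share it.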

How the results depend on the processing

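The directions of the named results mostly held, while the counts of calls depended on the tool and the libraries. The other settings for single genes were edgeR with 3 scalings, DESeq2, the replicate block, 3 groups without the set term and the Y-linked covariate. Of 685 log2 differences under them, 644 kept their direction and stayed called or uncalled as before, 2 lost the call, 29 gained one and 10 changed sign. With 1 library left out, 964 of 977 kept both, 4 lost and 4 gained the call, and 5 changed sign. Ercc6 for homozygous against wild type was the only one of these results called in the main fit, so each lost call was its own. The others kept their state by staying uncalled. They were picked for a small p and refitted on mostly the same libraries, so this tally says little about stability. Ercc6 also lost its call in 2 fits outside this tally, with only the libraries of the 2 groups compared and against the mean of the wild-type and heterozygous groups. Of 105 list results under other settings, 42 held, 61 lost the call and 2 changed sign. With 1 library left out, 172 of 202 held and 30 lost the call. The cause of these differences was not tested. For homozygous against wild type, the count of 8 features was 3 with only the libraries of these 2 groups in the fit, 5 with edgeR (TMM, RLE or upper-quartile factors, or a robust fit), 2 with limma-voom, 39 with DESeq2, 5 with edgeR on 3 groups without the set term, 2 with Y-linked reads as a covariate, and 4 against the mean of the wild-type and heterozygous groups. It was 2 to 11 with a library left out. For heterozygous against wild type, the count of 0 was 27 with DESeq2, 2 on 3 groups without the set term in either limma or edgeR, and 0 to 7 with a library left out. For homozygous against heterozygous, the count of 0 was 8 with only the libraries of these 2 groups, 207 with DESeq2, 17 and 39 on 3 groups without the set term in limma and edgeR, 5 with Y-linked reads as a covariate, and 0 to 3 with a library left out. List calls numbered 0 in every comparison with an estimated correlation and with the directional fry test, against 7, 9 and 5 (the fry test for mixed directions called 3, 1 and 1), and were 4 to 9, 4 to 11 and 3 to 8 with a library left out. Other filters, the other pseudocount and a log2 minimum of 1 moved no count by over 1.5 times. Leaving out a heterozygous library leaves 1, which is assumed to vary like the other groups. The fit of only the 2 groups compared was not run for heterozygous against wild type, because these groups share no set. Calb2, at few reads, changed sign for heterozygous against wild type, from -0.25 to 0.89 with edgeR TMM (0.90 with RLE and with upper-quartile factors) and 0.89 with DESeq2, and to 0.42, 0.38, 0.53, 0.65 and 0.00 without homozygous replicate 1, 4 or 5, heterozygous replicate 2 or wildtype replicate 1. Its left-out values ran from -1.66 to 0.65.

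The replicate number was also tried as a block, without the set term. The labels do not say that the numbers pair samples, and in the data 5 of 7 pairs of the same number had a correlation of deviations over 0.1, short of every pair. It was 0.014, 0.219 and -0.163 between homozygous and wild-type libraries, 0.146 and 0.185 between homozygous and heterozygous, and 0.178 and 0.22 between heterozygous and wild-type, while homozygous replicate 3 reached 0.451 with wild-type replicate 1, so not every sample correlated best with its own number. With the block, 4, 2 and 2 features were called in the 3 comparisons (homozygous against wild type, heterozygous against wild type, homozygous against heterozygous), and 4, 5 and 7 lists. Ercc6 was not called (-1.16, adjusted p = 0.673). For homozygous against wild type this fit turned the sign of the nuclear respiratory chain list (-0.216), the ribosomal protein list (-0.001), Sst (-0.22), Atp5o (-0.074), Cox7a2 (-0.25), Ndufb8 (-0.19), Mt-co2 (0.23) and Prdx1 (-0.062). It differs from the main fit both in the block and in the homozygous libraries used, so these turns cannot be put down to the block.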

Other observations

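The tests on features near Ercc6 and on features that set the wild-type libraries apart were chosen only after those features had been seen. A set of features separated the 3 wild-type libraries from all 8 libraries of the mutant line, whichever set they were normalized in. Comparing 3 with 8 libraries in limma, 6 features passed, 5 of them assembled features with no gene name. C3, the central complement component (chromosome 9, 9721105 to 9747167), held 1283 to 3034 normalized reads in the 8 libraries and 320 to 957 in the wild type (log2 difference 2.27, adjusted p = 0.0164). A feature on chromosome 5 (150490328 to 150491659) held 1.7 to 6.2 against 167 to 348 (adjusted p = 2.28e-05), and one on chromosome 13 (70188423 to 70203391) 10.0 to 30.5 against 0 to 1.1 (adjusted p = 0.0038). A candidate explanation is that the wild-type animals came from another stock or litter than the mutant line. Of 99 other arrangements of 3 against 8 libraries, drawn from all 165, 2 called at least 6 features and the highest 24. This goes with the hypothesis but does not separate it from an effect that 1 mutant copy already has. Sex, as read from Eif2s3y alone, is argued against for these features. Homozygous replicates 1 and 5 and heterozygous replicate 1 lacked Eif2s3y reads as the wild type did. Yet they lay with the other 5 libraries (2.2, 2.3 and 6.2 normalized reads of the chromosome 5 feature).

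Chance was also examined for the counts. Of the 10 splits of the 6 libraries in set 2 into 3 and 3, which are too few for a share under 0.05, the real one called 8 features and the highest other 1. For the list tests, the real split called 7 lists and 5 of the 10 splits called at least as many, the highest other 13. Over all 6 homozygous libraries without the set term, the real split called 7 features and 2 of 84 splits called at least as many. The other called 43 and set homozygous replicates 1 and 3 with wild-type replicate 1 against the rest, which points to a structure of the samples that cuts across the genotypes. These 3 libraries also lay lowest on the second principal component (-37.8, -31.1 and -36.0, 21% of the variance). Their meningeal fibroblast list means were 5.70, 5.38 and 6.00 log2 CPM, against 2.58 to 4.38 in the other libraries except homozygous replicate 5 (5.56), and their oligodendrocyte list means 6.62, 6.73 and 6.20, against 6.80 to 8.03 except homozygous replicate 5 (6.16).

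CSB acts when RNA polymerase stalls, so a hypothesis was that transcripts of longer genes are lost in homozygous tissue. Spearman's rho between log2 difference and genomic span over 9276 protein-coding genes was -0.12 against wild type but 0.071 against heterozygous libraries. With each library left out it ran from -0.16 to -0.069 in the first (the latter without wild-type replicate 2) and from 0.018 to 0.105 in the second. The prediction set beforehand was a negative rho in both, which was not met. The heterozygous libraries had 57.3% of the wild-type level of Ercc6, with all libraries scaled together, and could share such a loss. The second value therefore cannot decide whether a loss grows with length in homozygous tissue.

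Another hypothesis was a stretch of chromosome carried along with the mutation. Within 5 Mb of Ercc6, 12.77% of 94 features had an unadjusted p under 0.05 for homozygous against wild type, against 6.31% of the rest (two-sided Fisher's exact p = 0.0177). For homozygous against heterozygous the shares were 13.83% and 12.11% (exact p = 0.633). Neighbouring features are not independent, and the carriers share the region on 1 chromosome, so the hypothesis could not be decided. Chat and Slc18a3, cholinergic genes that share a locus there, were among the features behind the first share (log2 differences 2.45 and 1.33, adjusted p = 0.765 and 0.757), and were named after their values were seen.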
